A study of Macaca fascicularis with 81 samples.

How the data were processed

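Retinal cells of 8 young and 8 aged cynomolgus monkeys were picked singly by mouth pipette, lysed, and reverse transcribed with a modified SMART-seq2 chemistry in which barcodes and UMIs mark the 3' ends, per the labels' protocols. Up to 96 barcoded cells were pooled in a library. The deposited tables hold whole-number UMI counts per gene and cell, not normalized, for 81 libraries. CASAVA 1.8 and TopHat2 2.0.12 were used, per the submitters' processing notes. The genome build and annotation were not given in the sources used here. Of 21136 rows, 92 were ERCC spike-in RNAs, which held 13.4% of all UMIs and were left out of library sizes and tests, and 5046 of the 21044 gene rows were named by an Ensembl identifier only. Age, sex and monkey number were taken from the labels and design text. Libraries held 45 to 96 barcodes and 1536 to 16888506 UMIs (median 3753554).

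The study states 7461 cells, which is the number of barcodes in the files (3673 young, 3788 aged). Cells with at least 500 detected genes and 1000 UMIs were kept (7223), which removed all cells of the pigment epithelium library of young female 1. Cells were clustered over 2000 variable genes and 30 principal components with 15 neighbours by the Leiden algorithm (leidenalg 0.10.2, resolution 1.0), followed by a second round within each cluster on 15 components. Clusters were merged unless at least 10 genes differed by 4-fold or more. Of 24 first-round clusters, this made 41, of which 25 were named from marker genes: a class had to hold the most markers among the 10 leading genes and at least 3 among the leading 50. A cluster led by macrophage genes such as MRC1 and STAB1 was not named microglia-like. The merging rule, these details of naming and this exception were chosen after seeing the data, while the markers, gene lists, tests and most alternatives were fixed before the data were examined. No doublet caller was run, since cells were picked singly. As a check, 122 cells were marked as of mixed identity because markers exclusive to another class (5-fold over each other class) reached 50% of that class's median. This definition was chosen after a first, looser definition had marked most cells of some classes. The marked cells were kept, and their removal was an alternative. Among kept cells 55 held over 500000 UMIs.

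UMI counts were summed per monkey and class and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM factors, filterByExpr, sex as a covariate) with Benjamini-Hochberg adjustment at 0.05. A monkey entered with at least 10 cells of the class and a class was tested with at least 3 monkeys per age: rod-like and microglia-like cells (8 and 8 monkeys), bipolar-like (6 and 6), Müller glia-like (5 young and 3 aged) and T and NK cell-like cells (3 young and 4 aged). Cone-like cells did not reach this minimum and were tested with at least 5 cells per monkey (5 young and 6 aged), a choice made after seeing the data. The sums held 4925803 to 17466855 UMIs in rod-like cells. Positions were tested on sums of at least 5 cells with the monkey as a block. Gene lists (29) were tested with camera (limma 3.58.1, preset correlation of 0.01, at least 5 members) and again with an estimated correlation and with fry. Fold changes are log2 of aged over young. The named genes were up to 10 higher and 10 lower genes past the threshold with the smallest p, the 3 smallest p where fewer than 3 passed, the 4 members with the smallest p of a list past its test (of which the text gives some), and up to 5 each way for sex, interaction and position. Median shifts between TMM and RLE scaling were at most 0.0451 in size.

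Shares, depth and distances were compared over monkeys with exact two-sided permutation tests (12870 splits of 16 monkeys) or sign-flip tests within monkeys, adjusted over classes. The edgeR scripts were tested on simulated counts with 200 changed genes. Between ages they recovered 34% of 2-fold and 75% of 4-fold changes in rod-like cells (11320 genes), 0% and 20% in microglia-like (6588), 0% and 12% in bipolar-like (7517), 0% and 4% in Müller glia-like (11091), 1% and 5% in T and NK cell-like (7132) and 6% and 24% in cone-like cells (9204), and between dorsal and ventral rod-like cells 27% and 53% (11987). Outside rods, at most 24% of 4-fold changes were therefore recovered between the ages. Unchanged genes that were called numbered 8 in rod-like, 3 in Müller glia-like, 1 in microglia-like and 1 in T and NK cell-like cells. In bipolar-like and cone-like cells they numbered 0. The 3 false calls in Müller glia-like cells stood beside 0 recovered 2-fold and 4 recovered 4-fold changes. The 1 in T and NK cell-like cells stood beside 1 and 5. Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, no sex term, other cell minimums and cell filters, other Leiden resolutions (0.5 and 2.0), at most 20 cells per monkey, a block by monkey number, and leaving out each monkey, which left 2 monkeys of an age in part of the Müller glia-like and T and NK cell-like fits. Added after seeing the data were thinning to 5000 UMIs per cell, leaving out the 3 monkeys richest in ganglion-like UMIs, removing mixed cells from list tests and adding the Müller or ganglion share of UMIs per monkey to the rod fit. Cells were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Intervals of ratios cover counting error only, and the interval of the within-monkey slope came from 2000 bootstrap draws of monkeys.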

Results

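Single cells were profiled from the retinas of 16 cynomolgus monkeys (Macaca fascicularis), 8 young and 8 aged, with 4 females and 4 males at each age. Cells came from 4 neural retina positions (dorsal, ventral, nasal and temporal) and from a pigment epithelium position, which together made 81 libraries with 7461 cell barcodes. RNA was counted as unique molecular identifiers (UMIs, each marking a single captured transcript) per gene and cell. The deposited counts of a monkey summed to between 9847619 and 51232037 UMIs over its libraries. After low-quality barcodes were removed, 3486 cells from young and 3737 cells from aged monkeys were kept, with a median of 26099 UMIs and 2338 detected genes per cell. Clustering gave 4725 rod-like, 369 microglia-like, 246 Müller glia-like, 228 T and NK cell-like, 225 cone-like, 217 bipolar-like, 102 ganglion-like and 26 amacrine-like cells. The pigment epithelium position also gave 92 endothelial-like, 55 pigment epithelium-like, 42 fibroblast-like, 24 melanocyte-like and 13 pericyte-like cells. A neural position gave 1 endothelial-like cell, and 858 cells lay in clusters without a name.

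The first comparison asked which genes differed between aged and young monkeys within each cell class, with the monkey as the replicate. In rod-like cells, the dim-light photoreceptors, nuclear genes of oxidative phosphorylation were slightly higher in aged monkeys: 44 of 47 measured members were higher, with a median log2 difference of 0.16. UQCRB, a subunit of respiratory complex III, stood at 192 ± 41.4 CPM (UMIs per 1000000 after TMM scaling) in young and 244 ± 27.5 in aged monkeys (SD, n = 8 each). NDUFB7, a subunit of complex I, stood at 402 ± 48.5 and 512 ± 114. Genes of the cytosolic ribosome (46 of 50 higher, median 0.12), of the proteasome that degrades proteins (25 of 30, median 0.11) and of antioxidant defence (20 of 27, median 0.18) were higher as well. Among them were RPL5 with a log2 difference of 0.26 ± 0.11 (SE), PSMA5 with 0.36 ± 0.14 and PARK7, a redox-sensitive protein, with 0.44 ± 0.15. Genes of Müller glia, the supporting glia that recycle glutamate and retinoids, were lower in aged rod-like cells, with 12 of 15 members lower and a median of -0.76. RLBP1, a retinoid-binding protein, stood at 80.6 ± 28.2 CPM in young and 45.7 ± 23.4 in aged rod-like cells. GLUL, glutamine synthetase, stood at 133 ± 65.7 and 76.9 ± 24.4 CPM. RLBP1 averaged 4828 CPM in Müller glia-like cells of young monkeys. Limma's camera gave these lists adjusted p = 2.74e-06, 5.03e-05, 0.00334, 0.0267 and 8.93e-06 in the order named, over 29 lists.

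With an estimated correlation between genes none of the 5 lists of rod-like cells passed camera. Oxidative phosphorylation, ribosome and proteasome had adjusted p = 0.629 with an estimated correlation. There was an adjusted p = 0.547 with an estimated correlation for antioxidant defence and Müller glia. Antioxidant defence also did not pass camera without aged female 2 or 4 or young female 1, 3 or 4 (adjusted p = 0.0503 to 0.0974) or without the 3 monkeys richest in ganglion-like UMIs (adjusted p = 0.112), nor proteasome without young female 1 (0.0579). No member passed over all genes by edgeR. Adjusted over the list alone, 4 members of the Müller glia list (RLBP1, CRYM, GLUL and WIF1) and 0 members of the 4 other lists passed by edgeR. The lists were chosen because they passed camera on the same values, so these members are not separate evidence. Müller glia-like cells held 5.04% of neural retina UMIs in young and 3.08% in aged monkeys. With this share per monkey in the fit, an alternative chosen after seeing the data, the Müller glia list had a median of -0.33. Of the 11320 genes tested in rod-like cells, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 686 at an unadjusted p under 0.05, and DESeq2 called 1. A share of about 0.05 of unchanged genes falls under this unadjusted threshold by chance. Such counts, here and below, are therefore no evidence of a difference by themselves. The 3 genes with the smallest p did not pass. CALB1, a calcium-binding protein, stood at 39.6 ± 31.7 CPM in young and 243 ± 113 in aged monkeys (log2 2.74 ± 0.51, edgeR adjusted p = 0.752). The others were the dehydrogenase DHRS7 (0.74 ± 0.16, edgeR adjusted p = 0.752) and C15H9orf43 (-1.21 ± 0.28, edgeR adjusted p = 0.786). CALB1 passed without aged female 2, which stood at 16 CPM (edgeR adjusted p = 0.00296), and DHRS7 passed without young female 2 (edgeR adjusted p = 0.00931). CALB1 stood at 1409 CPM in cone-like cells of young monkeys. Cone markers as a group were 0.57 higher (log2) in aged than in young rod-like cells. Cone-like cells held 10.8% of neural retina UMIs in young and 12.7% in aged monkeys. The CALB1 level did not follow this share in each monkey. Aged male 3 stood at 390 CPM with a share of 2.66%, and young female 1 at 25.5 CPM with 29.3%. Young male 4 had the highest young level, 107 CPM, with a share of 22.4%. Whether cone RNA added to CALB1 was not tested.

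**Figure D1:**
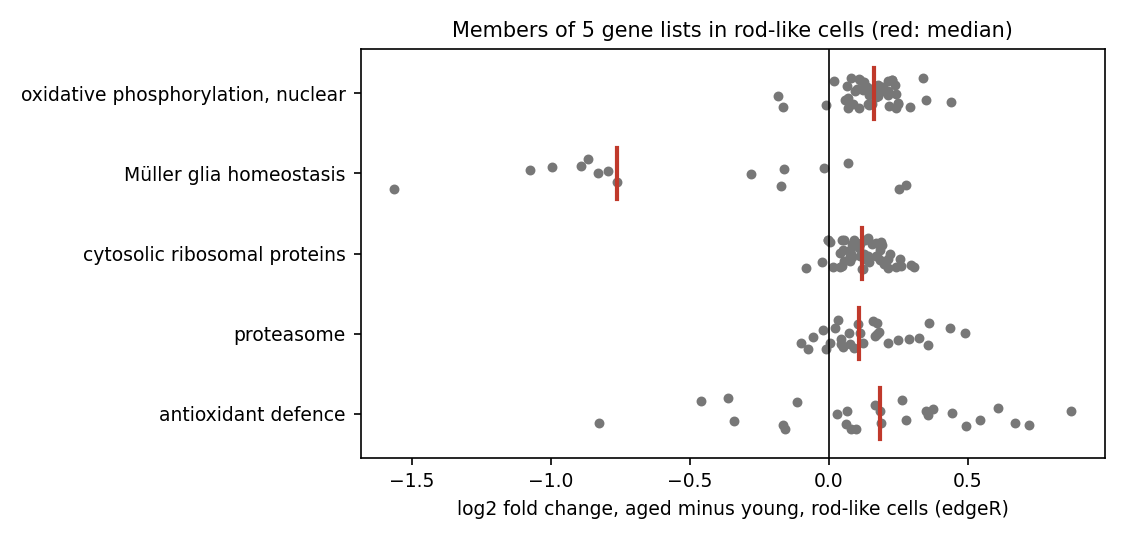
Each point is a gene of the named list, placed by its edgeR log2 fold change between aged and young monkeys in rod-like cells (horizontal axis), and red lines mark list medians. Medians ran from 0.11 to 0.18 for the lists that were higher, and the Müller glia list had a median of -0.76.

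In microglia-like cells, the resident immune cells of the retina, immediate early genes were higher in aged monkeys, with 18 of 20 members higher and a median log2 difference of 0.41. Their examples were BTG2, an antiproliferative gene, at 772 ± 196 CPM in young and 1057 ± 267 in aged monkeys (SD, n = 8 each), and the nuclear receptor NR4A1 at 793 ± 368 and 1186 ± 651. Endoplasmic reticulum stress genes (17 of 20 higher, median 0.30), with HERPUD1 at 554 ± 132 and 831 ± 306 CPM, were higher too. So were ribosomal protein genes (42 of 50, median 0.16), with RPL22 at a log2 difference of 0.54 ± 0.26 (SE). Proteasome genes were lower in 21 of 30 cases (median -0.18), with PSMB2 at 210 ± 124 and 101 ± 35.4 CPM. Rod phototransduction genes, markers of another cell class, were lower in 15 of 16 cases (median -0.36). Camera gave adjusted p = 0.00806 for immediate early, ribosomal and rod phototransduction genes and 0.0356 for proteasome and endoplasmic reticulum stress genes. None passed with an estimated correlation. Immediate early and proteasome genes had adjusted p = 0.40 with an estimated correlation. Endoplasmic reticulum stress genes had adjusted p = 0.293 and the ribosomal and rod phototransduction lists had adjusted p = 0.758. Leaving out single monkeys ended the camera call of endoplasmic reticulum stress genes for 14 of 16 monkeys (all but aged male 4 and young male 3, adjusted p = 0.0507 to 0.204). It ended that of proteasome genes for aged female 2, 3 and 4, aged male 2, young female 2 and 4 and young male 2 and 3 (adjusted p = 0.0615 to 0.187). Ribosomal genes did not pass without aged female 3, aged male 1 or young female 2 (camera adjusted p = 0.0567 to 0.0918), nor rod phototransduction genes without aged female 2 or 4 or young female 2 (0.124 to 0.642). In cells thinned to 5000 UMIs immediate early, proteasome and rod phototransduction genes did not pass (camera adjusted p = 0.921, 0.208 and 0.167), and without cells of mixed identity proteasome and rod phototransduction genes did not (0.0723 and 0.603). Rod phototransduction and endoplasmic reticulum stress genes did not pass without the 3 monkeys richest in ganglion-like UMIs (camera adjusted p = 0.494 and 0.122). Endoplasmic reticulum stress genes did not pass with at least 1000 genes per cell, nor proteasome genes without sex in the fit (camera adjusted p = 0.107 and 0.0717).

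Of 6588 genes tested in microglia-like cells, edgeR called 0, with 226 at an unadjusted p under 0.05, and DESeq2 called 2. Adjusted over the list alone, 0 members of the 5 lists passed by edgeR. Closest was SLC16A8, a lactate transporter of the pigment epithelium, with 1 UMI in the 8 young and 401 UMIs in the 8 aged monkeys. This gave a ratio per UMI of 265 (exact 95% interval 47.2 to 10481, counting error only) and an edgeR adjusted p of 0.0510. Aged female 1 and aged male 1 held 0 UMIs of it, and without either it passed (edgeR adjusted p = 0.0152 and 0.0154). Young male 4 held the 1 young UMI, and without this monkey the ratio was at least 77.8 against a floor of 3 UMIs. TRMU, a mitochondrial tRNA-modifying enzyme, followed with a log2 difference of 3.61 ± 0.81 (edgeR adjusted p = 0.40), and of 4.46 without young male 1 (edgeR adjusted p = 0.11), where the young mean was 4.56 CPM. ENSMFAG00000030598, an identifier the files do not pair with a name, had 0.83 ± 0.20 (edgeR adjusted p = 0.627). With RLE factors or at a Leiden resolution of 0.5 edgeR called 1 gene in this class, and without the low-count filter 2.

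In bipolar-like cells, the interneurons that receive photoreceptor input, the Müller glia list was lower in aged monkeys. Of its members 10 of 14 were lower, with a median log2 difference of -0.53. These monkeys were among those compared in rod-like cells, so this is not a separate set of animals. GLUL stood at 573 ± 259 CPM in young and 332 ± 142 in aged monkeys, CRYM at 140 ± 84.4 and 50.9 ± 58.6, and RLBP1 at 281 ± 106 and 133 ± 103 (SD, n = 6 each). Without aged male 1 the aged mean of CRYM was 30 CPM. This monkey stood at 156 CPM, and Müller glia-like cells held 9.56% of its neural retina UMIs. Over all monkeys that share was 5.04% in young and 3.08% in aged. Whether RNA of Müller glia set the difference in bipolar-like cells was not tested. Camera gave adjusted p = 0.0356 for this list and adjusted p = 0.544 with an estimated correlation. The list did not pass without aged female 4, aged male 4, young female 2 or 4 or young male 1 or 2 (camera adjusted p = 0.0534 to 0.211), or without the 3 monkeys richest in ganglion-like UMIs (0.272). Adjusted over the list alone, 0 members passed by edgeR. Over 7517 genes edgeR called 0, with 292 at an unadjusted p under 0.05, and DESeq2 called 2. The smallest p values, none passing, began with ENSMFAG00000037289, which had 1 UMI in young and 108 UMIs in aged monkeys (a ratio of 126, exact 95% interval 22.2 to 5025). Aged female 3 held 52 of these UMIs, 3 other aged monkeys held 0 to 2, and without aged female 3 the ratio was 74.0 (exact 95% interval 12.8 to 2975). It was 69.2 without young male 3 (12.2 to 2758) and at least 35.7, against a floor of 3 UMIs, without young female 4. PRTFDC1, a purine salvage homolog, had a log2 difference of -2.15 ± 0.57 (edgeR adjusted p = 0.999). ABR had 128 UMIs in young and 1 UMI in aged monkeys (a ratio of 110, exact 95% interval 19.3 to 4365, counting error only), and without aged male 3 the ratio was at least 27.2.

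In Müller glia-like cells, genes of gliosis, the reactive state of glia, were higher in aged monkeys, with 16 of 20 members higher and a median log2 difference of 1.02. GFAP, the intermediate filament of reactive glia, stood at 7.09 ± 7.94 CPM in 5 young and 86.9 ± 35.2 in 3 aged monkeys. S100A6, a calcium-binding protein, stood at 160 ± 67.9 and 765 ± 826. EDN2, an endothelin released by stressed photoreceptors in other settings, had 0 UMIs in the 5 young and 166 UMIs in the 3 aged monkeys. It was at least 96.4-fold higher against a floor of 3 UMIs over the young group, at least 150-fold without aged male 1 and at least 64.2-fold without young male 3. Ribosomal protein genes were higher in 49 of 50 cases (median 0.42), with RPS24 at 542 ± 284 and 1297 ± 348 CPM. Extracellular matrix genes were higher in 17 of 22 (median 0.76), with SPARC at 311 ± 130 and 853 ± 672 CPM. Heat shock genes were higher in 11 of 12 (median 0.56), with HSPB1 at 148 ± 97.9 and 556 ± 418 CPM. Rod phototransduction genes were lower in 16 of 20 cases (median -0.56), with SAG at 5718 ± 2658 and 3246 ± 2762 CPM. GRK1, of the same list, ran the other way with 2 UMIs in young and 70 UMIs in aged monkeys, all 70 in aged male 1. Without aged male 2 the aged means were 288 CPM for S100A6 and 467 CPM for SPARC. The aged mean was 1652 CPM for SAG without aged male 1 and 360 CPM for HSPB1 without aged male 4, and the young mean of GFAP was 3.72 CPM without young male 4. Camera gave adjusted p = 0.000915 for gliosis, 6.38e-07 for ribosome, 0.0102 for matrix, 0.0229 for heat shock and 0.00192 for rod genes. None passed with an estimated correlation. There was an adjusted p = 0.495 with an estimated correlation for matrix genes and adjusted p = 0.817 for the 4 others. Without aged male 2, which left 2 aged monkeys, gliosis, matrix, heat shock and rod phototransduction genes did not pass (camera adjusted p = 0.352, 0.137, 0.564 and 0.5002). Without aged male 4 heat shock and rod phototransduction genes did not (camera adjusted p = 0.208 and 0.0885). Without young male 1, rod phototransduction, heat shock and matrix genes did not pass (camera adjusted p = 0.162, 0.0882 and 0.0865), nor heat shock genes without young male 2 (0.0548) or matrix genes without young male 4 (0.0789). Gliosis genes did not pass in cells thinned to 5000 UMIs (camera adjusted p = 0.154), nor rod phototransduction genes without cells of mixed identity (0.05001). Of the 246 cells of this class, 41 were marked as of mixed identity. The class joined 3 clusters, with 78 young and 46 aged cells, 47 and 34, and 31 and 10 over all monkeys. Whether this makeup set the differences between the ages was not tested.

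EdgeR called 2 of 11091 genes in Müller glia-like cells, with 810 at an unadjusted p under 0.05. HSD17B2, an enzyme that inactivates estradiol and testosterone, rose from 38.5 ± 25.8 CPM in young to 371 ± 175 in aged monkeys (log2 3.44 ± 0.66, edgeR adjusted p = 0.0180, higher in 3 of 3 aged monkeys). ENSMFAG00000040162, which the files do not pair with a name, fell from 123 ± 151 to 1.83 ± 1.16 CPM (log2 -6.32 ± 1.21, edgeR adjusted p = 0.0180, lower than the young mean in 3 of 3 aged monkeys). Young female 2 held 0 UMIs of it, fewer than each aged monkey, and young male 1 stood at 334 CPM, without which the young mean was 70.6 CPM. Without aged male 2 its aged mean was 1.19 CPM. Neither gene passed without young female 2 (edgeR adjusted p = 0.161 for both), without young male 1 (0.0899 for HSD17B2 and 0.268 for the other) or without aged male 4 (0.244 and 0.158). HSD17B2 also did not pass without young male 2 or young male 3 (edgeR adjusted p = 0.0714 and 0.132), nor the other gene without young male 4 (0.0864). HSD17B2 did not pass with at least 1000 genes per cell or in cells thinned to 5000 UMIs (edgeR adjusted p = 0.0678 and 0.0535), nor the other gene without cells of mixed identity (0.0528). With the monkey number as a replicate block, neither of the 2 genes passed. EDN2 followed without passing (edgeR adjusted p = 0.0867), and passed without aged male 1 (edgeR adjusted p = 0.00972). Adjusted over the list alone, 3 gliosis members and 0 members of the 4 other lists passed by edgeR. These lists too were chosen by camera on the same values, so the 3 members are not separate evidence. The 3 aged monkeys were all male and 4 of the 5 young monkeys were male. With sex in the main fit, the sex term took up the values of young female 2, the only female. Beyond filtering, scaling and dispersion, the fold changes and p values by age in this class therefore compare 4 young with 3 aged males. The means and SDs of the young include young female 2. Without sex in the fit, with at least 5 cells per monkey, with at most 20 cells per monkey and at a Leiden resolution of 2.0 the count was 0. DESeq2 called 29 genes, the fit without a low-count filter 14, and leaving out single monkeys gave 0 to 18, with 18 without aged male 1, 4 without aged male 2 and 0 without aged male 4.

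In T and NK cell-like cells, lymphocytes found almost entirely at the pigment epithelium position, the interferon-induced gene IFI27 fell from 532 ± 448 CPM in 3 young to 34.1 ± 34.1 in 4 aged monkeys (log2 -4.64 ± 0.55, edgeR adjusted p = 0.000128, lower in 4 of 4 aged monkeys). Young female 2 stood at 1042 CPM, and without this monkey, which left 2 young monkeys, the young mean was 277 CPM and IFI27 did not pass (log2 -5.02, edgeR adjusted p = 0.9999). Without aged female 3 the aged mean was 18.8 CPM. IFI27 was the only gene called of 7132 (241 at an unadjusted p under 0.05), and without sex in the fit the count was 0. STX12, a vesicle-fusion protein, had a log2 difference of -4.19 ± 1.11 (edgeR adjusted p = 0.999) and of -5.76 without aged male 4, with an aged mean of 7.37 CPM, or 2.90 CPM without this monkey. DESI2, a peptidase, had 140 UMIs in young and 2 UMIs in aged monkeys, a ratio of 70.9 (exact 95% interval 19.3 to 592, counting error only), or at least 33.7 without aged male 4. Ribosomal protein genes were higher in aged cells (47 of 50, median log2 0.41), with RPL23 at 1081 ± 461 and 1921 ± 343 CPM. Immediate early genes were higher as well (13 of 17, median 0.56), with BTG2 at 150 ± 4.53 and 318 ± 98.6 CPM. Proteasome genes were lower in 23 of 30 cases (median -0.38), with PSMA4 at 279 ± 34.1 and 129 ± 48.5 CPM. Markers of other classes were also higher, with 5 of 5 Müller glia genes (median 1.88) and 13 of 14 rod phototransduction genes (median 0.57). PTGDS, the synthase of prostaglandin D, stood at 4.61 ± 3.0 and 61.1 ± 42.1 CPM. Camera gave adjusted p = 1.62e-05 for ribosome, 0.0161 for Müller glia and 0.0377 for the 3 others. None passed with an estimated correlation. Müller glia genes had adjusted p = 0.709 with an estimated correlation and the others had adjusted p = 0.863. Without young female 2, ribosomal, immediate early, proteasome and Müller glia genes did not pass (camera adjusted p = 0.8396 for the first 2, 0.335 and 0.0837). Without young male 2, immediate early, proteasome and Müller glia genes did not (camera adjusted p = 0.3303, 0.297 and 0.143), nor rod phototransduction genes without young male 4 (0.992). Without aged male 4, rod phototransduction and Müller glia genes did not pass (camera adjusted p = 0.490 and 0.448). Immediate early and proteasome genes did not pass without aged female 2 (camera adjusted p = 0.160 and 0.125) or aged female 3 (0.0942 and 0.0588), nor proteasome genes without aged male 2 (0.128) or Müller glia genes without aged female 3 (0.0588). Adjusted over the list alone, 0 members of these lists passed by edgeR.

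The next comparison asked whether genes differed between females and males. In rod-like cells the smallest p values belonged to RPS4X, an X-linked ribosomal protein gene, at 421 CPM in males and 677 in females (log2 0.68 ± 0.12 SE, higher in 8 of 8 females, edgeR adjusted p = 0.111), and DDX3X, an X-linked RNA helicase, at 60.8 and 111 CPM (0.89 ± 0.17, edgeR adjusted p = 0.135). Neither passed. EdgeR called 0 of 11320 genes, with 438 at an unadjusted p under 0.05, where DESeq2 called 9. EdgeR also called 0 genes in microglia-like (234 at an unadjusted p under 0.05), bipolar-like (458) and T and NK cell-like cells (243), where DESeq2 called 0, 43 and 21. In T and NK cell-like cells edgeR called 2 genes by sex without young male 4. The difference of the age effect between the sexes was tested in rod-like and microglia-like cells. EdgeR called 0 of 12095 and 0 of 7690 genes (530 and 357 at an unadjusted p under 0.05) and DESeq2 called 8 and 0. Müller glia-like cells were not compared by sex, since only 1 female reached the minimum of 10 cells.

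Positions were compared within monkeys. In rod-like cells, the smallest p between dorsal and ventral retina belonged to AP4B1, a subunit of a vesicle adaptor, at 88.6 ± 37.4 CPM dorsally and 45.1 ± 17.1 ventrally (SD, 16 monkeys, higher dorsally in 14, log2 0.96 ± 0.20, edgeR adjusted p = 0.151). NDUFA11, a complex I subunit, stood at 529 ± 135 and 718 ± 190 CPM (log2 -0.44 ± 0.10, edgeR adjusted p = 0.216). Both were named after their values were seen. EdgeR called 0 of 9706 genes between dorsal and ventral (496 at an unadjusted p under 0.05) and 0 between nasal and temporal rod-like cells (343), where DESeq2 called 4 and 0. Without young male 1 edgeR called 1 gene between dorsal and ventral. Between nasal and temporal microglia-like cells, with both positions in 4 monkeys, edgeR called 0 of 5655 genes (200 at an unadjusted p under 0.05) and DESeq2 called 1.

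The makeup of the neural retina was compared as the share of each class per monkey. Rod-like cells made up 81.1% ± 8.61 of kept neural cells in young and 78.2% ± 10.4 in aged monkeys (SD, n = 8 each; exact two-sided permutation test p = 0.538). Müller glia-like cells made up 5.26% ± 3.47 in young and 2.96% ± 2.47 in aged monkeys, lower than the young mean in 7 of 8 aged monkeys (exact permutation p = 0.150, adjusted p = 0.732). Microglia-like cells made up 5.29% ± 2.68 and 7.23% ± 5.52 (exact permutation p = 0.395). Cone-like cells made up 3.02% ± 3.52 and 4.68% ± 4.99 (exact permutation p = 0.470) and bipolar-like cells 3.82% ± 2.09 and 3.51% ± 1.78 (0.733). Ganglion-like cells made up 0.850% ± 1.29 and 2.55% ± 3.92 (exact permutation p = 0.282) and amacrine-like cells 0.509% ± 0.637 and 0.40% ± 0.405 (0.627). The difference turned for bipolar-like cells without young male 3 (0.341 percentage points, aged minus young) and for amacrine-like cells without young female 1 or young male 3 (0.00959 and 0.0501). At the pigment epithelium position, fibroblast-like cells, which express collagen and decorin genes, made up 6.31% ± 7.88 of cells in 7 young and 1.22% ± 1.03 in 8 aged monkeys (exact permutation p = 0.0538, adjusted p = 0.573). A cluster led by CPVL, FLT3 and HLA-DPB1, genes of antigen-presenting cells, made up 14.1% ± 11.8 and 5.51% ± 5.76 (exact permutation p = 0.0674, adjusted p = 0.573). T and NK cell-like cells made up 19.5% ± 25.3 and 14.2% ± 11.5 there (exact permutation p = 0.687) and pigment epithelium-like cells 1.84% ± 2.36 and 5.96% ± 11.0 (0.480). Melanocyte-like cells made up 2.55% ± 2.99 and 1.18% ± 1.25 (exact permutation p = 0.278) and endothelial-like cells 1.29% ± 1.67 and 11.1% ± 31.3 (1.0). The difference turned for T and NK cell-like cells without young female 2 (3.48 percentage points) and for endothelial-like cells without aged female 1 (-1.29), in which 88.5% of cells were endothelial-like against 0% in the other aged monkeys. Without aged female 4 the difference was 0.353 percentage points for pigment epithelium-like and 0.465 for ganglion-like cells, with aged means of 2.20% and 1.31%. Without young male 4 the young means of these classes were 1.16% and 0.436%. For cone-like cells the difference was 0.171 without aged male 2 and 2.56 without young male 4, for microglia-like cells 0.582 without aged male 4 and for Müller glia-like cells -1.51 without young male 3. For rod-like cells it ran from -4.72 without young male 4 to -1.07 without young female 3. It was -2.55 for fibroblast-like cells without young male 2 (young mean 3.78%), -4.64 for the CPVL cluster without young male 3 and -0.683 for melanocyte-like cells without young female 2 or 4. At Leiden resolutions of 0.5 and 2.0 it was -10.6 and -10.8 for fibroblast-like cells, at 0.5 it was 0.753 for pigment epithelium-like cells and at 2.0 it was -3.36 for melanocyte-like cells. The young mean was 10.7% for T and NK cell-like cells without young female 2 and 0.738% for endothelial-like cells without young male 2. No share passed adjustment over its classes, and which cells were picked can set these shares.

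**Figure D2:**
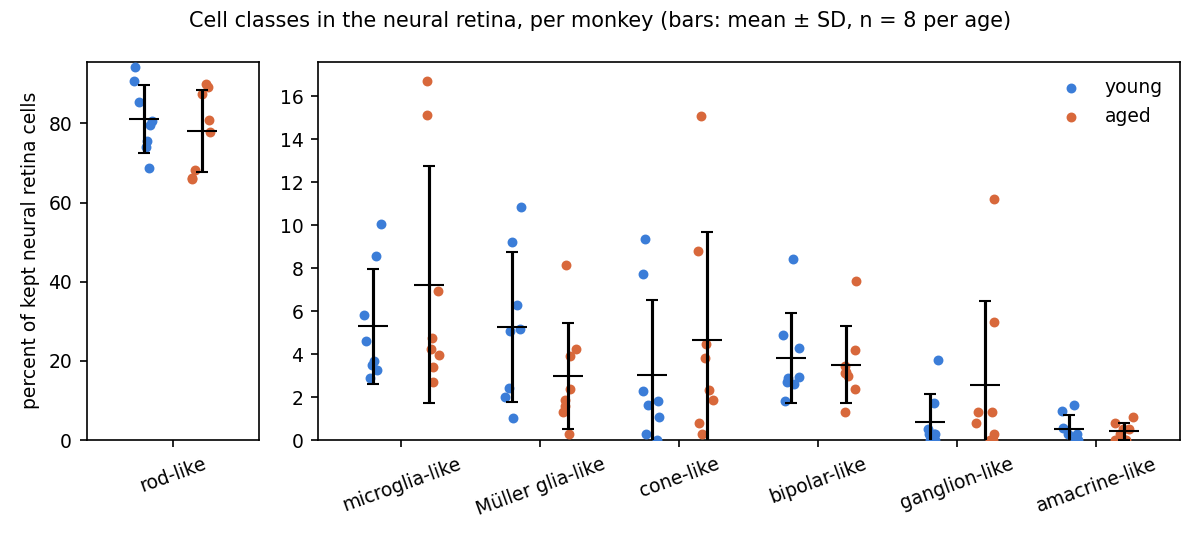
Points are single monkeys and bars give the mean ± SD of the share of each class among kept neural retina cells (vertical axes, percent, bars cut at 0) in 8 young and 8 aged monkeys. Shares overlapped between the ages in each class drawn, with rod-like cells at a mean of 81.1% in young and 78.2% in aged monkeys.

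A macrophage-like group of genes (VSIG4, STAB1, MRC1) led a cluster that was kept out of the microglia-like class by a rule set after seeing the data. This cluster made up 8.95% ± 7.65 of pigment epithelium cells in young and 5.30% ± 7.79 in aged monkeys (exact permutation p = 0.373), with an aged mean of 3.23% without aged female 4. Within the neural retina, Müller glia-like cells made up 4.96% ± 5.40 of cells dorsally and 2.27% ± 2.10 ventrally, higher dorsally in 10 of 16 monkeys (exact two-sided sign-flip permutation test p = 0.0510, adjusted p = 0.306). Bipolar-like cells made up 4.54% dorsally and 3.09% ventrally and microglia-like cells 4.86% and 6.90% (exact permutation p = 0.180 and 0.255). Cone-like cells made up 3.72% and 5.03%, ganglion-like cells 2.55% and 1.43% and rod-like cells 78.2% and 80.8% (exact permutation p = 0.53, 0.520 and 0.444). The difference turned for cone-like cells without young female 1 (0.070 percentage points, dorsal minus ventral) and for ganglion-like cells without aged female 4 (-0.0288) or at a Leiden resolution of 2.0 (-0.339). It was 0.892 for bipolar-like cells without young male 4, -0.715 for microglia-like cells without aged female 2 and -1.20 for rod-like cells without aged female 4. Between nasal and temporal retina the exact sign-flip permutation p was 0.645 for bipolar-like, 0.674 for cone-like, 0.750 for ganglion-like, 0.940 for microglia-like, 0.685 for Müller glia-like and 0.814 for rod-like cells. Against the neural positions of the same 15 monkeys, the pigment epithelium position held more T and NK cell-like cells (16.7% against 0.194%, exact permutation adjusted p = 0.000419). It held more pigment epithelium-like (4.04% against 0%, adjusted p = 0.00987), fibroblast-like (3.6% against 0%, 0.00180) and melanocyte-like cells (1.82% against 0%, 0.00552). It held 0% rod-like cells against 79.9%, 0% microglia-like against 6.0%, 0% bipolar-like against 3.73% and 0.144% Müller glia-like cells against 4.25% (exact permutation adjusted p = 0.000366 each). The microglia-like difference rests on the rule that kept the macrophage-like cluster out of this class. That cluster made up 8.95% and 5.30% of pigment epithelium cells in young and aged monkeys. The test therefore cannot decide whether microglia-like cells would differ without the rule. The pigment epithelium position held 0% cone-like against 3.59% (exact permutation adjusted p = 0.000419), 0% ganglion-like against 1.81% (0.00117) and 0% amacrine-like cells against 0.395% (0.00552). Without aged female 4 the difference from the neural positions was 2.02 percentage points for pigment epithelium-like and -1.14 for ganglion-like cells, and without young male 2 it was 2.32 for fibroblast-like cells. At a Leiden resolution of 0.5 it was 10.7 for pigment epithelium-like, 6.18 for fibroblast-like and 4.31 for melanocyte-like cells. At a resolution of 2.0 it was 6.26 for fibroblast-like, 4.55 for melanocyte-like and -3.42 for ganglion-like cells. Endothelial-like cells made up 6.51% against 0.0176% (adjusted p = 0.0682), with a difference of 0.646 without aged female 1.

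Ganglion-like cells, the output neurons of the retina, were rich in RNA, with a median of 423041 UMIs per cell against 22834 in rod-like cells. They held 60.2% of neural retina UMIs in aged female 4, 48.8% in aged male 4 and 41.4% in young male 4. The median cell of a monkey held 24087 ± 5662 UMIs in young and 29611 ± 7634 in aged monkeys (SD, n = 8 each; exact permutation p = 0.121). It held 2232 ± 269.7 and 2470.1 ± 325 detected genes (exact permutation p = 0.134). In rod-like cells the median was 21101 ± 5302 and 26397 ± 10443 UMIs (exact permutation p = 0.227) and 2100.0 ± 341 and 2334 ± 316 genes (0.170). Without young female 2 the aged cells held 325 more genes per cell and 346 more per rod-like cell (exact permutation p = 0.0228 and 0.0169, unadjusted). With each cell thinned to 5000 UMIs it was 1223 ± 109 and 1298 ± 110.1 genes (exact permutation p = 0.192). Thinning left out 184 rod-like cells of young and 173 of aged monkeys. Gene UMIs per spike-in UMI in rod-like cells, a measure of RNA content, stood at 3.44 ± 0.410 and 3.98 ± 0.772 (exact permutation p = 0.101).

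**Figure D3:**
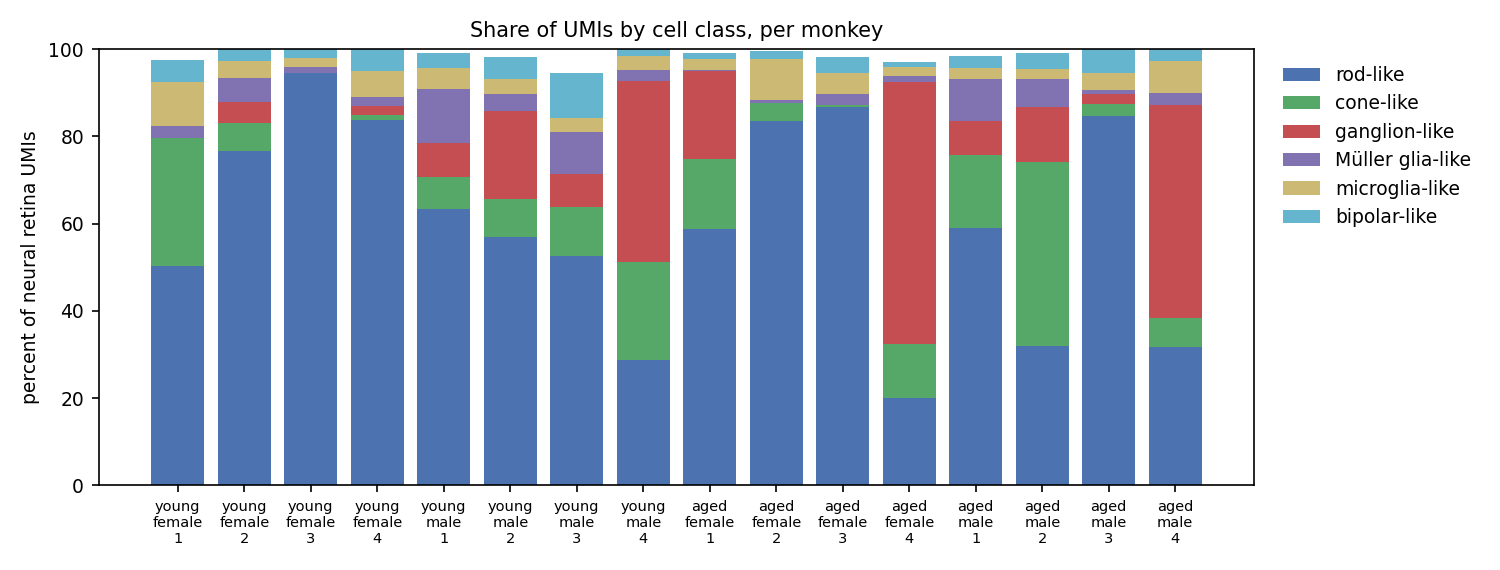
Stacked bars give the percent of neural retina UMIs held by 6 cell classes in each monkey (vertical axis, percent; 1 bar per monkey, named by age, sex and number). Ganglion-like cells held 60.2% in aged female 4, 48.8% in aged male 4 and 41.4% in young male 4.

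Variation between cells of a class was measured as 1 minus the Spearman correlation of each cell with the mean of the other cells of its monkey, after thinning to 5000 UMIs. In rod-like cells this distance was 0.643 ± 0.0170 in young and 0.630 ± 0.0190 in aged monkeys (SD, n = 8 each; exact permutation p = 0.165). Without aged female 1 the aged value was lower by 0.0179 (exact permutation p = 0.0490, unadjusted). It was 0.657 ± 0.0175 and 0.652 ± 0.0190 in microglia-like cells (7 and 8 monkeys, exact permutation p = 0.626) and 0.653 ± 0.0155 and 0.643 ± 0.0178 in bipolar-like cells (6 and 6, 0.361). It was 0.673 ± 0.0221 and 0.677 ± 0.00891 in Müller glia-like cells (5 and 3 monkeys, exact permutation p = 0.768) and 0.657 ± 0.00836 and 0.660 ± 0.0184 in T and NK cell-like cells (3 and 4, 0.80). Over genes with a mean of at least 1 UMI the age difference turned to -0.0390 in T and NK cell-like (exact permutation p = 0.0857) and -0.00447 in Müller glia-like cells (0.964). It also turned in microglia-like cells without young male 3 (0.000890), in Müller glia-like cells without aged male 4 or young male 4 (-0.000587 and -0.00341) and in T and NK cell-like cells without aged female 2 or young female 2 (-0.00350 and -0.00248). In bipolar-like cells it was -0.00345 without aged male 2. The adjusted p was 0.80 for each class.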

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

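The tests of depth per cell, of the Müller share of UMIs per monkey and of other splits were chosen after the results were seen, as was the size of slope that the first test below had to exclude. The test of the ganglion share was added after the data were seen, with its criterion written before its result. A single monkey stood far from the others of its age in 16 of 69 groups examined, where chance flags about 5% of groups, or 3.5.

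Genes of Müller glia were lower in aged than in young rod-like cells, with a median log2 difference of -0.76 (camera adjusted p = 8.93e-06, and adjusted p = 0.547 with an estimated correlation). Within monkeys, the list's summed level in rod-like cells rose by 0.0143 (log2) per percent of Müller glia-like UMIs in the library (65 libraries, permutation p = 0.296, bootstrap interval -0.0117 to 0.0481). The slope was above 0 in 13 of 16 monkeys. RNA pooled in the library would need a slope of 0.173 to account for the difference of -0.34 (log2, aged minus young) in the summed level of the list. This argues against RNA pooled in the library as the whole cause of the difference in the sum. The sum covered 18 genes and no member was tested alone, so the test does not decide the median of -0.76. Without cells of mixed identity the median was -0.77, which decides nothing, since only 2 cells of all other classes reached the level of Müller markers that marked a cell as mixed. With the Müller glia share of UMIs per monkey in the fit the median shrank to -0.33 (camera adjusted p = 0.0370; the list without this share had adjusted p = 0.547 with an estimated correlation), so RNA released by Müller glia of the same monkey before cells were picked may account for part of the difference, which cannot be told apart from age because the share itself differed (5.04% in young, 3.08% in aged monkeys). A lower expression in aged rods stays open and untested, and other splits of the monkeys do not exclude chance: 34 of 100 splits gave at least 5 lists past camera in rod-like cells, with up to 10 in another split.

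Lists of oxidative phosphorylation, ribosome, proteasome and antioxidant defence were higher in aged rod-like cells, but none passed camera with an estimated correlation (adjusted p = 0.547 for antioxidant defence and 0.629 for the others). With each cell thinned to 5000 UMIs, 4 of the 4 lists kept at least 50% of their median log2 difference. This argues against the greater weight of deep cells in the sums as the whole cause. Thinning keeps each gene's expected share of a cell's UMIs, so it cannot decide whether depth or RNA content set those shares. With the ganglion share of UMIs per monkey in the fit, 4 of the 4 lists did so too, which argues against RNA of ganglion-like cells in the same libraries as the whole cause. Antioxidant defence did not pass without the 3 monkeys richest in ganglion-like UMIs (camera adjusted p = 0.112), with a median of 0.187 against 0.183 with all monkeys. Leaving out aged female 2 or young female 1 or 3 (0% ganglion-like UMIs), young female 4 (2.08%) or aged female 4 (60.2%) ended this call as well. The lost call therefore does not single out ganglion-like RNA, and a part in this list stays open. Because 34 of 100 splits gave as many lists, chance remains open beside an age difference.

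Genes of pancreatic acinar cells appeared in rod-like cells, from a list of 22 genes, of which the files hold 15, chosen after they were noticed and before their spread was tested. In UMIs per 1000000, without TMM scaling, young female 1 stood at 2867 (455 without its ventral library) against 326 in the next young monkey, and aged male 4 at 393 against 259 in the next aged monkey. In the ventral library of young female 1, 48 of 54 rod-like and 40 of 41 other cells held at least 3 pancreas UMIs (55 of 68 rod-like cells did in the temporal library of aged female 4), and rod-like cells held 8609 and the other cells 981, a ratio of 0.114, which lay between the bounds set for RNA spread over all cells and RNA held by rod-like cells, so this cannot be told apart. A single rod-like cell held 47.6% and 10 cells 90.2% of the 16159 pancreas UMIs there (led by PLA2G1B with 2665 and CLPS with 1832 UMIs in rod-like cells), and without that cell rod-like cells held 3510 and the ratio was 0.280. RNA from another tissue during handling is a candidate source, and no biological explanation was tested.

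Bipolar-like cells made up 8.40% of neural cells in young male 3 (next 4.89%) and 7.41% in aged male 2 (next 4.19%), and ganglion-like cells 3.74% in young male 4 (next 1.72%). At the pigment epithelium position, aged female 4 held 32.3% pigment epithelium-like cells (next 6.94%), young female 2 held 72.2% T and NK cell-like cells (next 26.2%) and aged female 1 held 88.5% endothelial-like cells (next 0%). Young female 2 had a median of 2843 genes per cell (next 2328) and 2882 per rod-like cell (next 2217). DHRS7 stood at 552 CPM in rod-like cells of young female 2 (next 364), TRMU at 35.9 CPM in microglia-like cells of young male 1 (next 8.37) and PRTFDC1 at 665 CPM in bipolar-like cells of young male 1 (next 283). Genes with 1 or 2 UMIs in a group stood out by construction: SLC16A8 at 1.82 CPM in microglia-like cells of young male 4, ABR at 1.33 CPM in bipolar-like cells of aged male 3 and DESI2 at 2.31 CPM in T and NK cell-like cells of aged male 4, each against 0 in the other monkeys of that age.

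For the counts above 0, other splits of the same monkeys did not exclude chance. In Müller glia-like cells, 15 of 56 splits gave at least the 2 genes of the real split (highest other 9) and 18 gave at least its 5 lists (highest other 10). Splits that labelled young female 2, the only female, as aged compared fewer aged-labelled males than the real split. These counts therefore mix unlike fits. In T and NK cell-like cells, 9 of 34 splits gave at least the 1 gene of the real split (highest other 7) and 7 gave at least its 5 lists (highest other 6). In microglia-like cells 11 of 100 splits gave at least 5 lists (highest other 10), and in bipolar-like cells 77 of 100 gave at least 1 list (highest other 7). A count of 0 cannot be tested in this way, since each split gives at least 0. For the age counts of 0 genes, the highest other split of 100 gave 1 in rod-like, 1 in microglia-like, 2 in bipolar-like and 2 in cone-like cells, and for the 0 lists of cone-like cells 6. For the sex counts of 0 genes it gave 8 in rod-like, 7 in microglia-like, 2 in bipolar-like, 1 in cone-like and, of 34 splits, 14 in T and NK cell-like cells, and for the interaction counts of 0 it gave 1 in rod-like and 1 in microglia-like cells. For positions, 25 swaps gave at most 0 genes in rod-like cells for both contrasts, and 8 swaps, too few for a share under 0.05, gave at most 0 for microglia-like cells against a real count of 0.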

How the results depend on the processing

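Alternatives chosen after seeing the data were the thinned cells, the fits without the 3 ganglion-rich monkeys, the list tests without mixed cells and the share covariates. Of 2157 values under an alternative, 1879 kept their direction and side of the threshold. For the 18 genes named by smallest p between the ages, 384 of 427 alternatives did so, 23 lost and 20 gained a call and 0 changed sign. List members and genes named for sex or position were not among these 18. For 21 lists past camera 293 of 414 did so and 121 lost the call. The cause was not tested unless stated. In simulated counts at most 24% of 4-fold changes between the ages were recovered outside rods.

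With DESeq2, age counts were 1 in rod-like, 2 in microglia-like, 2 in bipolar-like, 29 in Müller glia-like and 3 in cone-like cells. Its sex counts were 9 in rod-like, 43 in bipolar-like, 21 in T and NK cell-like and 2 in cone-like cells. Its interaction count was 8 in rod-like cells, and its position counts 4 between dorsal and ventral rod-like and 1 between nasal and temporal microglia-like cells. Without the low-count filter, age counts were 2 in microglia-like, 14 in Müller glia-like and 13 in cone-like cells, sex counts 5 in T and NK cell-like and 6 in cone-like cells, and the interaction count 3 in microglia-like cells. With RLE factors or at resolution 0.5 the microglia-like age count was 1. The Müller glia-like age count was 0 without sex in the fit, with at least 5 cells, with at most 20 cells per monkey and at resolution 2.0, and 1 with at least 1000 genes per cell. The T and NK cell-like age count was 0 without sex in the fit, and its sex count 1 with at least 5 cells.

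Whether monkey numbers pair the monkeys is not stated in the labels, and they were treated as names because the deviations of same-numbered monkeys correlated at -0.0506 to 0.144, not over 0.1 in each pair. In rod-like cells 9 of 16 monkeys matched their own number best, where 4 would by chance, so a weak pairing was not excluded. With the number as a replicate block the age counts were 0 in rod-like, 1 in microglia-like, 0 in bipolar-like, 1 in Müller glia-like (neither of the 2 genes called without it, edgeR adjusted p = 0.0814 and 0.176), 1 in T and NK cell-like and 0 in cone-like cells. Without the replicate block (the monkey) the position counts stayed at 0.

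With an estimated correlation the number of lists was 0 in each class, and with fry 0 in each class but microglia-like cells (1). Lists in microglia-like cells numbered 3 without mixed cells, 2 in thinned cells and 3 without the ganglion-rich monkeys, and in bipolar-like cells 0 without those monkeys. Leaving out single monkeys, lists numbered 4 to 9 in rod-like, 1 to 6 in microglia-like, 0 to 1 in bipolar-like, 2 to 9 in Müller glia-like (9 without aged male 1, 2 without aged male 2 and 3 without aged male 4), 1 to 6 in T and NK cell-like (1 without young female 2 and 2 without young male 2) and 0 to 1 in cone-like cells. Age genes then numbered 0 to 1 in rod-like, microglia-like, cone-like and T and NK cell-like cells (0 without young female 2) and 0 to 18 in Müller glia-like cells (18 without aged male 1, 4 without aged male 2 and 0 without aged male 4), sex genes 0 to 1 in cone-like and 0 to 2 in T and NK cell-like cells (2 without young male 4), and dorsal against ventral genes 0 to 1 in rod-like cells. Rod-like lists numbered 8 without aged male 1 and 9 without young male 4.

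Leaving out single monkeys, the age difference was 152 to 325 genes per cell and 168 to 346 per rod-like cell, the highest of each without young female 2, with an unadjusted permutation p then under 0.05. The age difference of the distance was -0.0179 (without aged female 1, with an unadjusted permutation p under 0.05) to -0.00861 in rod-like, -0.00860 to 0.000890 in microglia-like, -0.00341 to 0.0112 in Müller glia-like and -0.00350 to 0.0109 in T and NK cell-like cells. With genes of at least 1 UMI it was -0.00447 in Müller glia-like and -0.0390 in T and NK cell-like cells. In percentage points, the age difference of shares was -8.20 to 3.48 for T and NK cell-like, -1.29 to 11.4 for endothelial-like, -0.205 to 0.0501 for amacrine-like and -0.871 to 0.341 for bipolar-like cells. Dorsal minus ventral it was -1.93 to 0.070 for cone-like and -0.0288 to 1.47 for ganglion-like cells. Nasal minus temporal it was -0.591 to 0.0274 for bipolar-like, -0.00211 to 0.491 for cone-like, -0.149 to 0.636 for ganglion-like, -1.53 to 0.833 for microglia-like and -2.16 to 0.445 for rod-like cells. At resolution 2.0 ganglion-like cells differed by -0.339 (dorsal minus ventral) and -1.07 (nasal minus temporal) and rod-like cells by 0.773 (nasal minus temporal).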

Other observations

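Cone-like cells, the photoreceptors of daylight and color vision, were compared with at least 5 cells per monkey (5 young and 6 aged), a test chosen after the data were seen. The smallest p values, none passing, began with ENAH, an actin regulator with 0 UMIs in young and 572 UMIs in aged monkeys, at least 94.7-fold higher against a floor of 3 UMIs over the young group, or at least 59.5-fold without young male 4 (edgeR adjusted p = 0.150; it passed without aged female 4, edgeR adjusted p = 0.0169). CLIC2 stood at 24.4 ± 33.5 CPM in young and 0.292 ± 0.443 in aged monkeys (edgeR adjusted p = 0.531; the young mean was 10.5 without young female 2 and the aged mean 0.127 without aged female 2) and MBD4, a DNA glycosylase, at 131 ± 64.4 and 32.4 ± 16.9 CPM (log2 -2.01 ± 0.46, edgeR adjusted p = 0.697). EdgeR called 0 of 9204 genes by age, with 325 at an unadjusted p under 0.05, where DESeq2 called 3, and 0 of the gene lists passed camera. By sex edgeR called 0 genes (304 at an unadjusted p under 0.05) and DESeq2 called 2, and without aged male 4 edgeR called 1.

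Markers of other classes in rod-like cells were more abundant in libraries that held cells of that class. In UMIs per 1000000, without TMM scaling, cone markers had a median of 19.3 in rod-like cells of 28 libraries without cone-like cells and 919 in the other libraries, ganglion markers 12.8 (38 libraries without the class) and 498, bipolar markers 38.0 (8 libraries) and 110, microglia markers 85.3 (2 libraries) and 246, and the Müller glia list 818 (11 libraries) and 1048. These medians were computed after the data were seen. Across libraries of the same monkey, log2 of this value plus 1 in rod-like cells rose per percent of UMIs held by the class by 0.176 for cone, 0.123 for ganglion, 0.214 for bipolar and 0.212 for microglia markers (65 libraries, permutation within monkeys p = 0.0001 each). For the Müller glia list the slope was 0.0143 (permutation p = 0.296), and it was above 0 in 13 of 16 monkeys.

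Cells were not spread at random over the wells of the neural libraries. Wells 77 to 96 held 72.9% of cone-like, 80.4% of ganglion-like and 43.4% of Müller glia-like cells, against 16.7% of rod-like and 20.9% of all kept cells.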
